A study of Mus musculus with 157 samples.

How the data were processed

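The labels of the series name 157 samples of mouse E14 embryonic stem cells treated with retinoic acid (RA). Of these, 53 have a column in the 4 tables used here: crosslinked ChIP-seq libraries of total RNA polymerase II (antibody to the N-terminal domain, NTD) and of its forms phosphorylated at serine 5 (Ser5p) or serine 2 (Ser2p) of the C-terminal repeat. The samples of input, H3K27ac, H3K27me3 and H3K4me1 are not analysed here. Each library was placed in its group by antibody and hours of RA, and took its replicate number, from the labels. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

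Per the submitters' processing notes, the work used the mouse build mm10 and the fly build dm6 with Bowtie2, SAMtools, MACS2 and DESeq2. The counting tool and all versions are not given in the sources used here. Track names in the labels speak of uniquely mapped reads without duplicates and say that 2 h NTD replicate 3 was left out of a merged track. The authors deposited raw read counts, whole numbers per RefSeq transcript, for NTD and Ser5p within 1 kb on either side of the transcription start site (TSS) and for NTD and Ser2p over gene bodies. Beside each raw count the deposited normalized signal is the raw count times a factor that is the same for every transcript of a library. The authors' log2 fold changes against 0 h, which are shrunken values, and their adjusted p-values are also in these tables. A further 49 deposited columns with per-sample or per-group values were not used.

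The tables hold 33687 transcripts (NTD at TSS), 33746 (Ser5p at TSS), 33968 (NTD over gene bodies) and 33985 (Ser2p over gene bodies). Transcripts without a symbol (80, 90, 104 and 106), with 0.0650, 0.0761, 0.0168 and 0.0166 percent of the counts, stayed in library sizes and tests. They were left out of counts of genes and of the gene lists. Dates stood in place of 58 symbols throughout and were kept as they were. Accessions of 33290, 33334, 33541 and 33556 transcripts matched the RefSeq gene table of GRCm38 (mm10), which gave gene positions, 1-based. Isoforms and overlapping genes share reads, and 11519, 11534, 10194 and 10193 transcripts have exactly the counts of another transcript, so numbers of transcripts exceed numbers of independent regions. Strand is not read by ChIP-seq, so genes whose windows overlap (such as Vax2 and Vax2os) cannot be told apart.

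Counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3 with limma 3.58.1, data.table (version 1.17.8) and, as an alternative, DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All libraries counted in the same way entered the same fit, with time as a factor and no replicate block. Each time was tested against 0 h, and all times together with an F test, at a Benjamini-Hochberg adjusted p of 0.05. After filtering, 31868, 32774, 31843 and 32123 transcripts were tested, with a common biological coefficient of variation of 0.138, 0.141, 0.118 and 0.0899. The change in the NTD ratio of gene body to TSS was tested with limma on log2 CPM (counts scaled to the library total) with a pseudocount of 0.5 CPM. Whether Ser5p or Ser2p changed otherwise than NTD was tested as the interaction of antibody and time in edgeR. In the text a ± after a CPM is an SD, and a ± after a log2 change is its standard error (SE).

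The 24 gene lists were RA metabolism and receptors, anterior Hox, posterior Hox, Hox cofactors, naive pluripotency, general pluripotency, formative and primed state, neural progenitor and neuron, primitive endoderm, mesoderm and primitive streak, trophoblast, two-cell-like, fibroblast, Polycomb-associated homeobox and patterning genes, FGF-ERK feedback, WNT targets, BMP and TGF-beta targets, LIF-STAT3 targets, immediate early genes, heat shock and p53 response, cell cycle, epithelial junctions, mesenchymal genes and reference genes. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, on log2 CPM with a prior count of 2, adjusted over the lists of a table and time. A symbol with several transcripts was represented by the transcript with the highest mean count. The genes named are the 6 with the largest rise and the 6 with the largest fall per table at 6 h and at 72 h, among those past the threshold with a mean of at least 5 CPM, each library beyond all 0 h libraries and no predicted gene, then 2 members per list at those times, and 18 genes named at all times (among them Rarb, Cyp26a1, Dhrs3, Stra6, Hoxb1, Hoxa2, Cdx1, Meis2, Gata6, Pax6, Sox1, Pou5f1, Nanog, Sox2, Zfp42, Esrrb and Actb). Some of these genes are not reported here. Where another gene is named as a member of a list or of a count, it was chosen after its values were seen. Groups, tests, lists, this rule and the alternatives named next were fixed before the data were examined.

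The alternatives were DESeq2, DESeq2 size factors in edgeR, library totals, no filter, a pseudocount of 2 CPM, a replicate block, only the libraries of the 2 times compared, and leaving out each library in turn. A further alternative, stricter thresholds, was meant for tables that hold only comparisons and was not run. Added after seeing the data were the authors' scale factors, 1 transcript per gene, leaving out both NTD libraries with extra promoter signal, 5 further gene families, contrasts between later times, and an enrichment index as a covariate. The index is the log2 ratio, per library, of counts in the densest 5 percent of genes to counts in the sparsest 50 percent. No replicate pair had counts within sampling noise of each other, so no library was counted as a duplicate.

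The total count per library was 1088159 to 3210580 for NTD at TSS, 1504737 to 3347830 for Ser5p at TSS, 11684907 to 25696364 for NTD over gene bodies and 18045745 to 28745658 for Ser2p. The tests were first run on simulated counts with 200 transcripts changed by known folds. At 6 h they recovered 45.9 percent of 2-fold and 90.7 percent of 4-fold changes for NTD at TSS (31230 transcripts), 48 and 93 percent for Ser5p, 89 and 100 percent for NTD over gene bodies, and 94 and 99 percent for Ser2p. At 72 h the shares were 37.4 and 90 percent, 34 and 86 percent, 86 and 97 percent, and 83 and 98 percent. For the interaction of Ser5p and NTD they were 11 and 77.6 percent at 6 h and 8.16 and 55.6 percent at 72 h, for that of Ser2p and NTD 61.6 and 98 percent and 63 and 94 percent, and for the ratio 4 and 56 percent and 4 and 44 percent. In these simulated counts a 2-fold change at a promoter was therefore missed more often than found. Data with more changed transcripts were not simulated.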

Results

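Mouse E14 cells are embryonic stem cells kept on gelatin in serum with leukaemia inhibitory factor (LIF). They were treated with 1 µM retinoic acid (RA), the vitamin A derivative that drives their differentiation, for 2, 4, 6, 24, 48 or 72 h. Crosslinked chromatin was immunoprecipitated and sequenced with antibodies to 3 forms of RNA polymerase II (Pol II). These were total Pol II, through its N-terminal domain (NTD), Pol II phosphorylated at serine 5 of its C-terminal repeat (Ser5p, the form concentrated at promoters), and Pol II phosphorylated at serine 2 (Ser2p, the form that accumulates along transcribed genes). NTD was sequenced in 2 libraries at 0, 2, 24 and 72 h and in 3 libraries at 4, 6 and 48 h. Ser5p and Ser2p had the same numbers, with 3 libraries at 2 h. Around transcription start sites (TSS), NTD totalled 1088159 to 3210580 reads per library and Ser5p 1504737 to 3347830. Over gene bodies, NTD totalled 11684907 to 25696364 reads and Ser2p 18045745 to 28745658. The series concerns contacts of promoters during the activation of developmental genes, and the time course asks where Pol II was gained, lost or modified after RA. Each time was compared with 0 h, where every antibody had 2 libraries.

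The RA-degrading enzyme genes Cyp26a1 (chromosome 19, positions 37697738 to 37701536 of mm10) and Cyp26c1 (37685112 to 37693320) lie next to each other. Rarb, which encodes a receptor of RA, spans positions 16430839 to 17082331 of chromosome 14. Cdx1, a caudal-type homeobox gene, spans positions 61018862 to 61036199 of chromosome 18. Hoxa2, a patterning gene of the hindbrain, is at 52162417 to 52164831 of chromosome 6. Egr1, an immediate early transcription factor gene, is at 34861207 to 34864956 of chromosome 18. Pou5f1 (35506032 to 35510777 of chromosome 17) encodes the pluripotency factor OCT4, and Tdgf1 (110939608 to 110946158 of chromosome 9) a co-receptor of Nodal.

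**Figure D1:**
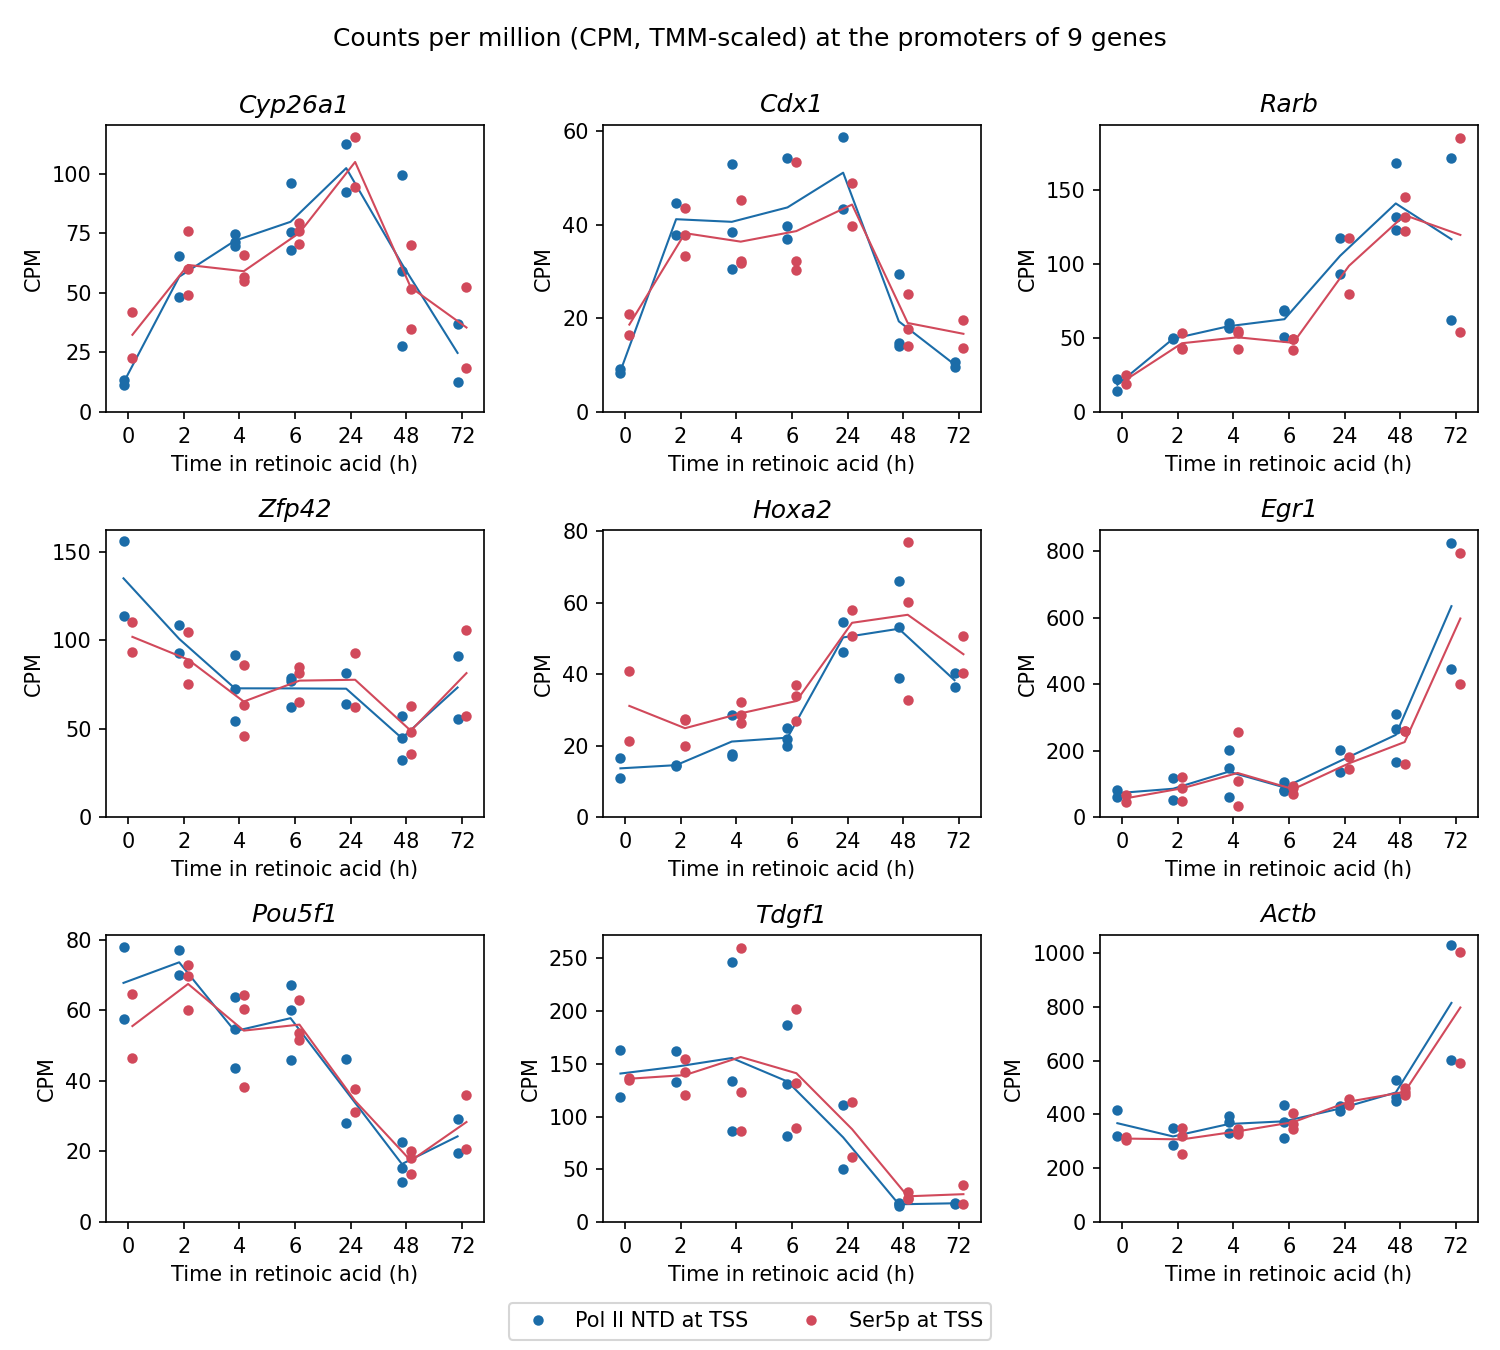
CPM (reads scaled to the library total with TMM) at the TSS against hours of RA, drawn as evenly spaced categories, for 9 genes, with a point per library and a line through the means, NTD in blue and Ser5p in red. NTD at Cyp26a1 stood at 12.3 CPM at 0 h and 79.8 CPM at 6 h, and at Tdgf1 it stood at 141 CPM at 0 h and 17.8 CPM at 72 h.

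The early times asked which promoters gained or lost total Pol II within 6 h of RA. At 6 h (n = 3) NTD rose 6.45-fold at Cyp26a1, from 12.3 ± 1.61 to 79.8 ± 14.5 CPM (log2 change 2.69 ± 0.33, adjusted p = 2.65e-06 by edgeR). It rose 5.00-fold at Cdx1 (2.32 ± 0.29, adjusted p = 3.70e-06) and 3.35-fold at Rarb (1.75 ± 0.28, adjusted p = 1.53e-04). It also rose at Stra8, an RA-induced gene of meiotic entry (3.55-fold, 1.83 ± 0.27), at Acp5, which encodes tartrate-resistant acid phosphatase (3.27-fold, 1.71 ± 0.24), and at H2-Bl, an MHC class I gene (3.11-fold, 1.64 ± 0.25). At 2 h (n = 2) Cyp26a1 (2.20 ± 0.36), Cdx1 (2.22 ± 0.32) and Rarb (1.40 ± 0.31) were already higher, with adjusted p of 0.00137, 9.81e-05 and 0.0216. These 6 genes kept their call at 6 h under all alternatives run.

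Of the 21 measured genes of RA metabolism and receptors, 6 rose at 6 h and none fell, and adjusted over the list alone 8 rose. Among them were Nrip1, a corepressor of nuclear receptors, and Dhrs3, which encodes a retinaldehyde reductase (1.24 ± 0.26, adjusted p = 0.00514). The list had a median log2 change of 0.23 and a camera adjusted p = 8.91e-06, which was adjusted p = 0.159 with an estimated correlation. At 2 h 2 members rose (7 adjusted over the list alone), with a camera adjusted p = 7.58e-07 and adjusted p = 0.128 with an estimated correlation. At 4 h 8 members rose (8 higher and 1 lower adjusted over the list alone), with a camera adjusted p = 7.16e-07 and adjusted p = 0.127 with an estimated correlation. Dhrs3 was not called at 6 h without 0 h replicate 1 (0.98, adjusted p = 0.286) or without 0 h replicate 4 (1.59, adjusted p = 0.0600).

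Among 15 anterior Hox genes, which pattern the hindbrain and neck, 2 rose at 6 h, such as Hoxa4 (1.56 ± 0.30, adjusted p = 0.00111). Hoxb2, Hoxb3 and Hoxb5 fell. Adjusted over the list alone 5 rose and 4 fell. The list had a median of -0.13, or 0.11 with the authors' scale factors, while camera pointed up (adjusted p = 0.393). Hoxa4 lost its call without 0 h replicate 4 (1.19, adjusted p = 0.410), where Hoxb2 stood at 0.05, Hoxb3 at 0.18 and Hoxb5 at -0.19, none of them called. Of 9 Hox cofactors, Pbx2 rose (1.37 ± 0.30, 1 adjusted over the list alone), a call lost without 0 h replicate 4 (1.10) or 6 h replicate 3 (1.16). The cofactors had a camera adjusted p = 0.0460, and adjusted p = 0.159 with an estimated correlation. Of 20 naive pluripotency genes, Zfp42, a marker of the naive state also called Rex1, fell (-0.89 ± 0.21, adjusted p = 0.0142, 2 adjusted over the list alone). Its call was lost without 0 h replicate 4 (-0.66, adjusted p = 0.603) or 6 h replicate 3 (-0.79, adjusted p = 0.130).

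NTD fell most at 6 h at Scnn1g, a sodium channel subunit gene (67.8 ± 83.4 CPM at 0 h, -3.70 ± 0.56), Pak3, a kinase gene (-3.38 ± 0.57), and Ntsr1, the neurotensin receptor gene (-3.37 ± 0.52). It also fell at Prlr, the prolactin receptor gene (-3.30 ± 0.51), and Sorcs3, a sorting receptor gene (-2.95 ± 0.50). The adjusted p of these 5 genes lay between 9.31e-05 and 2.71e-04. Each call came from 0 h replicate 4, without which the changes were -0.74 at Scnn1g, -0.87 at Pak3, -0.73 at Ntsr1, -0.70 at Prlr and -0.94 at Sorcs3. The 118 transcripts called lower at 6 h belonged to 118 genes on 20 chromosomes. Their median NTD signal was 108 CPM in 0 h replicate 4, 85.6 CPM in 72 h replicate 3 and 12.3 to 15.2 CPM in the other 15 NTD libraries. Ser5p at the same promoters had medians of 14.9 to 20.9 CPM over its 18 libraries. With 0 h replicate 4 left out, 2 transcripts were lower at 6 h.

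**Figure D2:**
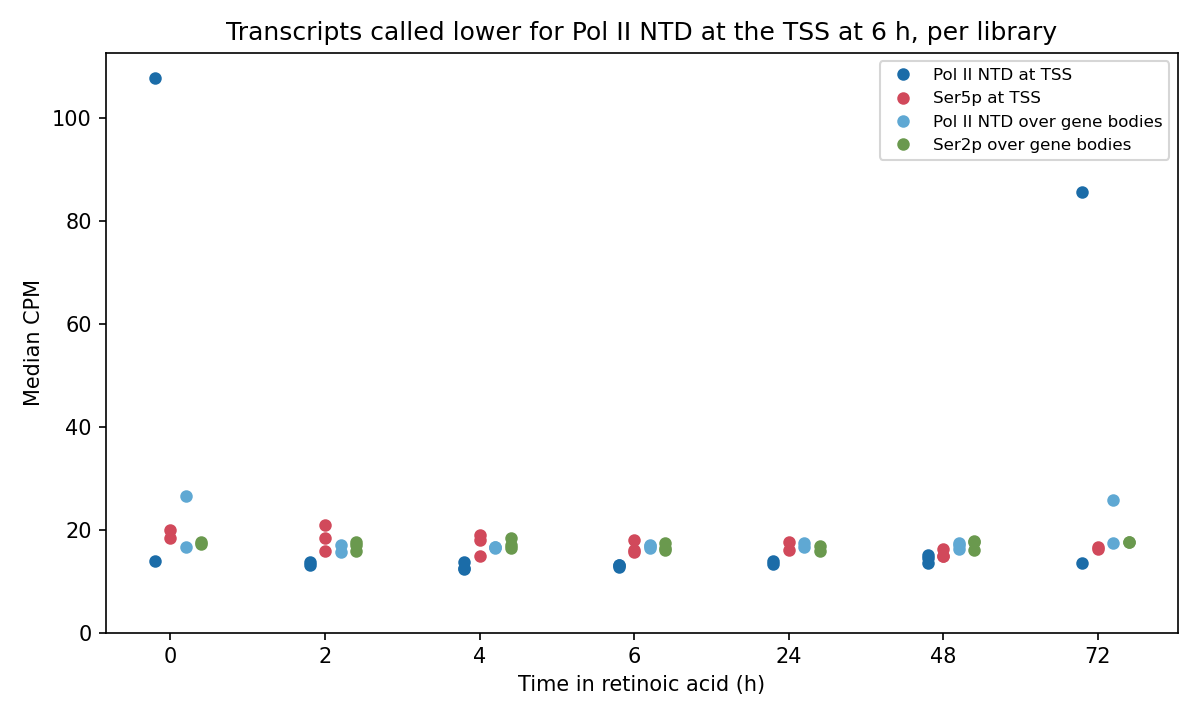
Median CPM, per library and for each of the 4 tables, of the 118 transcripts at which NTD at the TSS was called lower at 6 h, against hours of RA drawn as evenly spaced categories. NTD at the TSS stood at 108 CPM in 0 h replicate 4 and 85.6 CPM in 72 h replicate 3, and at 12.3 to 15.2 CPM in the other libraries.

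In all, edgeR called NTD at the TSS higher at 17 and lower at 85 transcripts at 2 h, 87 and 139 at 4 h, and 113 and 118 at 6 h (78 and 118 genes). Single libraries moved these counts by over 1.5 times. At 2 h there were 13 higher and 169 lower without 0 h replicate 1, and 2 and 0 without 0 h replicate 4. The 2 h calls numbered 2 and 0 without 2 h replicate 1, and 3 and 0 without 2 h replicate 4. At 4 h there were 43 and 188 without 0 h replicate 1, 16 and 2 without 0 h replicate 4, 36 and 103 without 4 h replicate 3, and 55 and 104 without 4 h replicate 4. At 6 h there were 43 and 179 without 0 h replicate 1, 20 and 2 without 0 h replicate 4, 75 and 95 without 6 h replicate 1, 63 and 93 without 6 h replicate 3, and 34 and 2 without both 0 h replicate 4 and 72 h replicate 3. DESeq2 called 3 higher and 0 lower at 2 h, 60 and 8 at 4 h, and 71 and 0 at 6 h. With the authors' scale factors the split was 3 higher and 106 lower at 2 h and 28 higher and 108 lower at 4 h.

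The later times asked how Pol II at promoters changed as differentiation went on. At 24 h (n = 2) NTD had risen 3.62-fold at Hoxa2 (1.86 ± 0.26, adjusted p = 1.21e-05), and Cyp26a1 stood 8.35-fold above 0 h. Of 13 BMP and TGF-beta targets, 5 rose, such as Id1 (0.99 ± 0.22), Id2 and Smad6, and 10 rose adjusted over the list alone. The list median, 0.84, came with a camera adjusted p = 8.48e-12 (adjusted p = 0.00515 with an estimated correlation). Of 9 Hox cofactors, Pbx2 and Meis1 rose (3 adjusted over the list alone, median 0.73). Camera gave the cofactors an adjusted p = 6.33e-05, and adjusted p = 0.0131 with an estimated correlation. Of the RA list 7 rose (7 adjusted over the list alone), with a camera adjusted p = 3.74e-06 and adjusted p = 0.0669 with an estimated correlation. Among the anterior Hox genes 4 rose, such as Hoxa4 and Hoxa5, and Hoxb3 was called lower (5 higher and 2 lower adjusted over the list alone). The call of Hoxb3 came from 0 h replicate 4, without which its change was 0.72 (adjusted p = 0.562). The list median was -0.22, or 0.18 with the authors' scale factors, while camera pointed up (adjusted p = 0.0127, adjusted p = 0.290 with an estimated correlation). Pou5f1 fell at 24 h (-0.89 ± 0.24, adjusted p = 0.0359), as 1 of 10 general pluripotency genes (6 adjusted over the list alone). That list had a camera adjusted p = 0.0211, and adjusted p = 0.312 with an estimated correlation. The 24 h calls numbered 2 and 2 BMP and TGF-beta targets, 0 cofactors, 5 and 3 genes of the RA list and 0 general pluripotency genes without 0 h replicate 4 and without 24 h replicate 3.

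At 48 h (n = 3) NTD stood 7.49-fold above 0 h at Rarb (2.90 ± 0.28, adjusted p = 3.13e-10) and 3.89-fold at Hoxa2 (1.96 ± 0.25, adjusted p = 1.91e-07). It had fallen at Tdgf1 (-3.05 ± 0.32, adjusted p = 1.61e-09), Pou5f1 (-2.03 ± 0.24, adjusted p = 4.69e-08) and Zfp42 (-1.65 ± 0.22, adjusted p = 4.28e-07). General pluripotency genes fell at 7 of 10 promoters (7 adjusted over the list alone), with a camera adjusted p = 1.61e-07 and adjusted p = 0.0377 with an estimated correlation. Of 9 Hox cofactors 5 rose (6 adjusted over the list alone), with a camera adjusted p = 5.25e-06 and adjusted p = 0.0124 with an estimated correlation. Anterior Hox genes rose at 6 promoters, and Hoxb3 and Hoxb5 were called lower (7 and 2 adjusted over the list alone), with a camera adjusted p = 3.33e-05 and adjusted p = 0.0456 with an estimated correlation. Without 0 h replicate 4 Hoxb3 stood at 1.07, Hoxb5 at 0.26 and Hoxb2 at 1.79, against 0.25 at Hoxb2 with all libraries. Cell cycle genes fell at 5 of 20 promoters, such as the replication helicase genes Mcm2, Mcm3 and Mcm6 (1 higher and 9 lower adjusted over the list alone). The cell cycle list had a camera adjusted p = 6.00e-04, and adjusted p = 0.364 with an estimated correlation. Values of other single genes and of lists at 48 h were not recomputed without each library.

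By 72 h (n = 2) NTD had risen 8.89-fold at Egr1 (72.0 ± 14.7 to 635 ± 268 CPM, 3.15 ± 0.34, adjusted p = 9.53e-09) and 7.08-fold at the immediate early gene Fosb (2.82 ± 0.28). Cyr61, which encodes a matricellular protein (2.62 ± 0.27), Egr3 (2.59 ± 0.28) and the keratin gene Krt18 (2.49 ± 0.27) rose too. NTD fell most at Lrrc2 (-3.02 ± 0.44) and at its neighbour Tdgf1 (141 ± 31.2 to 17.8 ± 0.456 CPM, -2.98 ± 0.35, adjusted p = 5.58e-08). It fell at the inhibin subunit gene Inhbb (-2.67 ± 0.38), at Nphs1, which encodes nephrin (-2.33 ± 0.40), at the threonine dehydrogenase gene Tdh (-2.31 ± 0.32) and at Platr8, a pluripotency-associated long noncoding RNA (-2.28 ± 0.30). Pou5f1 (-1.44 ± 0.25, adjusted p = 7.72e-05) and Sox2 (-1.33 ± 0.25, adjusted p = 2.04e-04) were below 0 h. Sox2 was not called with the authors' scale factors (-1.13, adjusted p = 0.0779). Nanog had a change of -0.46 ± 0.27 (adjusted p = 0.356) and Esrrb one of -0.90 (adjusted p = 0.178). Rarb was 6.00-fold above 0 h (2.59 ± 0.29). Cyp26a1 (0.88 ± 0.40, adjusted p = 0.179) and Cdx1 (0.19 ± 0.38, adjusted p = 0.850) were not called and had fallen between 24 and 72 h (-2.18 ± 0.32 and -2.33 ± 0.30).

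Of 16 immediate early genes, 13 rose and Myc fell at 72 h (13 and 1 adjusted over the list alone). The list median, 1.38, came with a camera adjusted p = 7.89e-13 (adjusted p = 0.0119 with an estimated correlation). Of 9 Hox cofactors, 5 rose, such as Meis1 (2.15 ± 0.26), Meis2 and Pbx2 (5 adjusted over the list alone). The list median, 1.05, came with a camera adjusted p = 3.00e-05 (adjusted p = 0.0119 with an estimated correlation). Pbx2 (1.05) was not called without 0 h replicate 4 (0.80) or 72 h replicate 1 (0.61). Of 10 general pluripotency genes, Tdgf1, Sox2, L1td1, Sall4, Utf1 and Pou5f1 fell (7 adjusted over the list alone). The list median, -1.10, came with a camera adjusted p = 2.15e-07 (adjusted p = 0.0321 with an estimated correlation). Of 13 BMP and TGF-beta targets 6 rose (7 higher and 1 lower adjusted over the list alone). The list median, 0.85, came with a camera adjusted p = 6.37e-06 (adjusted p = 0.0286 with an estimated correlation). Of 18 primitive endoderm genes, which mark an extraembryonic lineage, 9 rose, among them the basement membrane genes Lama1, Lamb1, Col4a1 (2.07 ± 0.31) and Col4a2 (11 adjusted over the list alone). The list median, 0.99, came with a camera adjusted p = 7.02e-08 (adjusted p = 0.0608 with an estimated correlation). The primitive endoderm factor gene Gata6 (1.30 ± 0.39, adjusted p = 0.0262) was not called without 0 h replicate 1 (0.94, adjusted p = 0.223) or 72 h replicate 1 (0.68, adjusted p = 0.364).

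Of 15 anterior Hox genes, 6 rose at 72 h, such as Hoxa2, Hoxa4, Hoxb4 and Hoxc4 (7 adjusted over the list alone). The list median, 0.55, came with a camera adjusted p = 6.19e-05 (adjusted p = 0.0562 with an estimated correlation). Of 15 posterior Hox genes Hoxd9 alone rose (1 adjusted over the list alone), and the list had a camera adjusted p = 0.976. Its median was -0.05, or 0.10 with the authors' scale factors, and Hoxd9 was not called without 0 h replicate 4 (0.92) or 72 h replicate 3 (1.21). Of the RA list 5 rose (5 adjusted over the list alone), with a camera adjusted p = 7.84e-04 and adjusted p = 0.115 with an estimated correlation. Of 20 naive pluripotency genes Zfp42, Fgf4, Nr0b1, Dppa4, Tdh and Tcl1 fell (8 adjusted over the list alone). The list median, -0.59, came with a camera adjusted p = 5.55e-05 (adjusted p = 0.214 with an estimated correlation). Zfp42 was not called without 0 h replicate 4 (-0.59), without 72 h replicate 1 (-0.54) or with the authors' scale factors (-0.66). Of 9 mesenchymal genes Snai1, Vim, Cdh2, Twist1 and Zeb2 rose (5 adjusted over the list alone). The list median, 0.95, came with a camera adjusted p = 8.29e-04 (adjusted p = 0.0689 with an estimated correlation). Of 13 genes of the heat shock and p53 response 5 rose (6 adjusted over the list alone), with a camera adjusted p = 6.59e-04 and adjusted p = 0.355 with an estimated correlation. Twist1 lost its call without 72 h replicate 3 (1.21), and the heat shock gene Hspa1b without 72 h replicate 3 (0.43) or 0 h replicate 4 (0.95).

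The formative and primed state list had Sox4, Dnmt3b and Sox3 higher and 5 members lower of 14, such as Etv4, Foxd3 and Lef1 (3 and 5 adjusted over the list alone, camera adjusted p = 0.113). Of 23 neural genes, Nes and Irx3 rose (3 adjusted over the list alone, camera adjusted p = 0.405). Sox1 stood at 0.04 and Pax6 at 0.43 (adjusted p = 0.458), and Irx3 was not called without 0 h replicate 4 (1.06). Of 29 Polycomb-associated homeobox and patterning genes, Dlx1, Irx2 and Irx5 rose and Barhl1 fell (3 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.373). Barhl1 was not called without 0 h replicate 1 (-1.12), 0 h replicate 4 (-1.25) or 72 h replicate 3 (-0.65), nor Irx2 without 0 h replicate 4 (1.05) or 72 h replicate 1 (1.11). The fibroblast list had the smooth muscle genes Tagln and Acta2 higher of 12 (2 adjusted over the list alone), with a camera adjusted p = 0.0102 and adjusted p = 0.0635 with an estimated correlation. The trophoblast list had the keratin genes Krt18 and Krt8 higher of 12 (2 adjusted over the list alone, camera adjusted p = 0.126), with Krt8 not called without 72 h replicate 3 (1.09). Tbx6 was the 1 called gene of 15 in the mesoderm list (1 adjusted over the list alone, camera adjusted p = 0.406), and its change was 0.23 without 72 h replicate 3 and 0.64 without 0 h replicate 4. Of 11 FGF-ERK feedback genes Egr1 and Dusp4 were higher and Etv1, Etv4 and Etv5 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.527). Of 11 WNT targets Nkd1 and Axin2 were higher and Lef1 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.527), where Axin2 was not called without 0 h replicate 4 (1.23) or 72 h replicate 3 (1.12).

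The lists of LIF-STAT3 targets, two-cell-like, epithelial junction and cell cycle genes did not pass camera at 72 h. Junb was higher of 9 LIF-STAT3 targets (1 adjusted over the list alone, camera adjusted p = 0.976), a call lost without 72 h replicate 3 (0.87). Zfp352 was higher and Eif1a lower of 2 two-cell-like genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.976). Zfp352 was not called without 0 h replicate 1 (1.69), 0 h replicate 4 (1.61) or 72 h replicate 3 (1.22). Eif1a was not called without any 1 of 0 h replicates 1 (-0.56) and 4 (-0.64) and 72 h replicates 1 (-0.46) and 3 (-0.78). Cldn6 was higher and Epcam lower of 9 epithelial junction genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.976). Cldn6 was not called without 0 h replicate 4 (0.96) or 72 h replicate 3 (1.01), nor Epcam without 0 h replicate 1 (-0.61) or 72 h replicate 1 (-0.54). Ccnd2 was higher and Ccnd1 and Ccne1 lower of 20 cell cycle genes (1 and 4 adjusted over the list alone, camera adjusted p = 0.0954), and Ccnd2 was not called without 0 h replicate 4 (1.06) or 72 h replicate 3 (0.70). Of 13 reference genes 3 rose, such as Actb and B2m (3 adjusted over the list alone), with a camera adjusted p = 0.0186 and adjusted p = 0.499 with an estimated correlation. Actb, which encodes beta-actin, was at 1.15 ± 0.25 (adjusted p = 0.00130), and was not called without 0 h replicate 1 (1.01) or 72 h replicate 3 (0.73).

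In all, NTD at the TSS was higher at 299 and lower at 185 transcripts at 24 h, 1489 and 1567 at 48 h, and 1803 and 1105 at 72 h (1264 and 813 genes). Over all times together 4759 transcripts were called. At 24 h there were 144 higher and 217 lower without 0 h replicate 1, 73 and 17 without 0 h replicate 4, and 20 and 1 without 24 h replicate 3. At 48 h there were 793 and 1089 without 0 h replicate 1, 687 and 550 without 0 h replicate 4, and 875 and 1371 without 48 h replicate 2. At 72 h there were 1032 and 715 without 0 h replicate 1, 1152 and 513 without 0 h replicate 4, and 650 and 916 without 72 h replicate 3. Leaving out both 0 h replicate 4 and 72 h replicate 3 gave 161 and 38 at 24 h, 929 and 678 at 48 h, and 365 and 436 at 72 h. DESeq2 called 164 and 15 at 24 h, and 1029 and 1042 at 48 h. With a replicate block there were 112 higher and 170 lower at 24 h. With the authors' scale factors the splits were 623 and 102 at 24 h, 1201 and 366 at 48 h, and 1063 and 151 at 72 h. The median log2 change of all transcripts stood, with these factors, at 0.13 at 4 h, 0.25 at 6 h, 0.38 at 24 h, 0.20 at 48 h and 0.14 at 72 h.

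**Figure D3:**
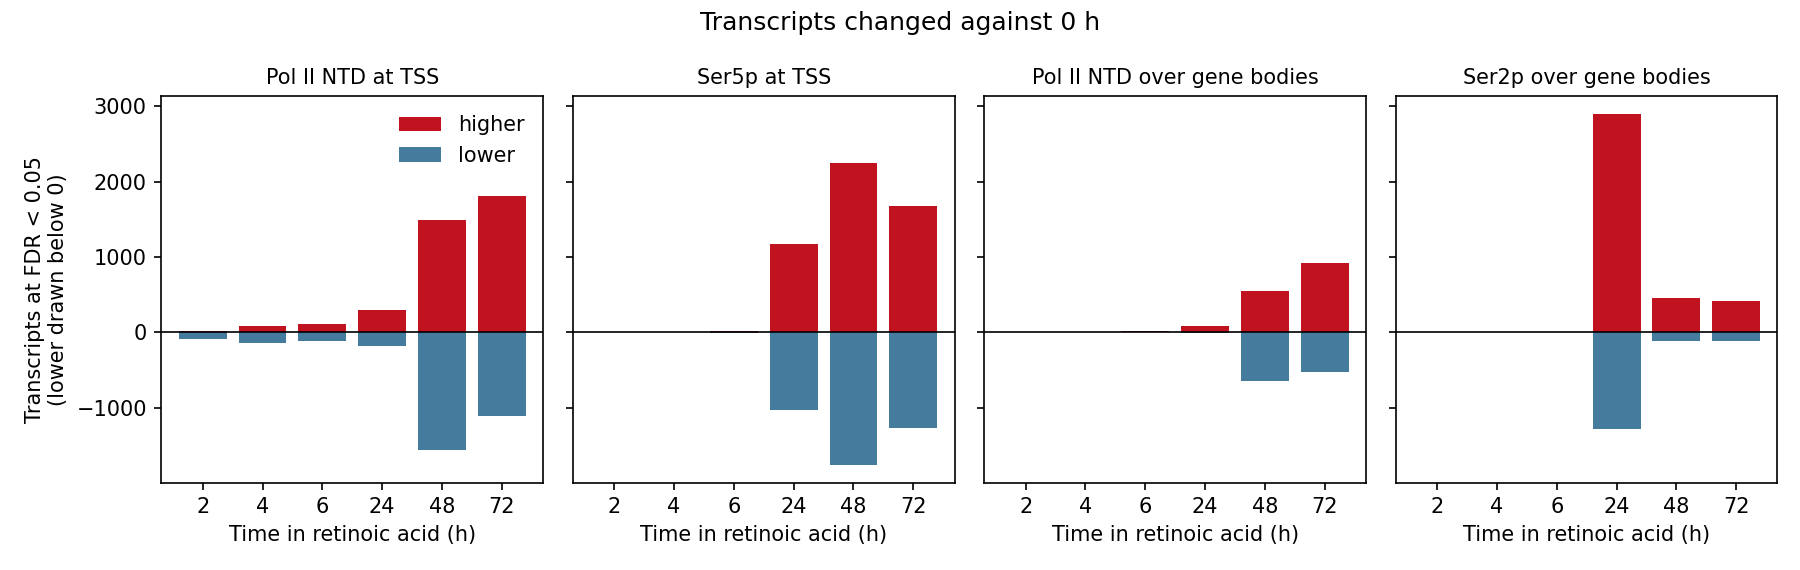
Number of transcripts called higher (bars above 0) and lower (bars below 0) than at 0 h by edgeR in each of the 4 tables, against hours of RA drawn as evenly spaced categories. At 72 h 1803 transcripts were higher and 1105 lower for NTD at the TSS, and 411 were higher and 110 lower for Ser2p over gene bodies.

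Ser5p at promoters asked where the initiation-linked form changed. At 6 h (n = 3) it rose at Cd37, a tetraspanin gene (chromosome 7, 45233632 to 45239340), 3.02-fold (1.59 ± 0.26, adjusted p = 0.00376). It rose at Ppdpf (1.42 ± 0.23), the linker histone gene Hist1h1e (1.39 ± 0.29), Acp5 (1.25 ± 0.22) and Pmepa1, a TGF-beta-induced gene (1.22 ± 0.25). Cyp26a1 (1.24 ± 0.29, adjusted p = 0.0664) and Rarb (1.10, adjusted p = 0.139) were not called. No call of these 5 genes was left without 6 h replicate 1, where Cd37 stood at 1.42, Ppdpf at 1.41 and Acp5 at 1.25 (adjusted p = 0.0635 each). Ppdpf was also not called without 0 h replicate 4 (1.16, adjusted p = 0.474), nor was Acp5 (1.13) or Hist1h1e (1.04). Pmepa1 (1.01 and 1.43) was not called without 0 h replicate 1 or 4. Hist1h1e was not called without 6 h replicate 3 (1.43) or with the authors' scale factors.

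Stem cells keep the Polycomb-associated genes and the posterior Hox genes under Polycomb repression. At 6 h Ser5p had medians of -0.83 over 30 of the former and -0.79 over 16 of the latter, with 0 genes called and 21 and 11 lower adjusted over the list alone. Camera gave these lists an adjusted p = 1.35e-10 and 4.04e-07, and adjusted p = 0.663 with an estimated correlation for both. Ser5p in 0 h replicate 4 stood above 0 h replicate 1 (46.0 and 21.6 CPM over the former, 50.5 and 25.7 CPM over the latter), with 13.6 to 25.4 and 16.2 to 26.4 CPM at 6 h. Without 0 h replicate 4 the 6 h medians were -0.20 and -0.44. By 24 h (n = 2) 9 and 8 of them had fallen (23 and 15 adjusted over the list alone, medians -0.94 and -1.01). Their camera adjusted p was 2.85e-06 and 1.30e-05, with adjusted p = 0.633 with an estimated correlation. None of these genes was called at 24 h without 0 h replicate 4 (medians -0.40 and -0.56), 24 h replicate 2 (-0.72 and -0.91) or 24 h replicate 3 (-1.05 and -1.18). At 24 h Ser5p had risen at 10 of 13 genes of the heat shock and p53 response, such as Mdm2 and Cdkn1a (10 adjusted over the list alone). This list had a camera adjusted p = 1.07e-06, and adjusted p = 0.558 with an estimated correlation. Ser5p had also risen at 7 of 13 BMP and TGF-beta targets and at 7 of 16 immediate early genes (7 and 9 adjusted over the list alone). Camera gave them an adjusted p = 3.76e-05 and 1.27e-05, and adjusted p = 0.420 with an estimated correlation for both. Of the RA list 6 rose and Aldh1a1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0564). Of the anterior Hox genes 3 rose, such as Hoxa4 and Hoxb1 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.516). Of the heat shock, BMP, immediate early, RA and anterior Hox genes, 0, 2, 0, 5 and 2 were called higher at 24 h without 0 h replicate 4, and 0, 2, 0, 3 and 1 without 24 h replicate 3. They were 3, 4, 2, 6 and 1 without 0 h replicate 1, and 0, 3, 0, 5 and 3 with the enrichment index as a covariate.

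At 72 h (n = 2) Ser5p fell at 24 of 30 Polycomb-associated genes. Among them were the patterning genes Pax7 (69.1 ± 44.7 to 10.7 ± 0.506 CPM, -2.65 ± 0.43, adjusted p = 5.92e-05) and Barhl2 (-2.38 ± 0.43). It fell at 12 of 16 posterior Hox genes, such as Hoxc9 (-2.49 ± 0.41, adjusted p = 7.09e-05). Adjusted over the list alone 27 and 15 fell, with medians of -1.26 and -1.65. These lists had a camera adjusted p = 3.97e-15 and 5.89e-11, and adjusted p = 0.300 with an estimated correlation for both. The largest fall was at Fendrr, a noncoding RNA gene beside Foxf1 (chromosome 8, 121054882 to 121083110), from a mean of 58.8 to 7.78 ± 0.955 CPM (-2.88 ± 0.44, adjusted p = 2.53e-05). Ser5p also fell at Six3os1 (-2.87 ± 0.41), the ETS factor gene Fev (-2.82 ± 0.43), Nrg3, which encodes a neuregulin (-2.70 ± 0.49), and Nkx1-1 (-2.64 ± 0.36). The Ser5p median over the Polycomb-associated list was 46.0 CPM in 0 h replicate 4 and 21.6 CPM in 0 h replicate 1. With 0 h replicate 4 left out the list had a median of -0.80 with 5 genes called, and Nrg3 (-1.96, adjusted p = 0.0518) and Hoxd11 (-1.57, adjusted p = 0.0558) were not called. In the 72 h libraries the median was 12.5 and 11.8 CPM, while NTD at the same promoters had medians of 6.36 to 9.90 CPM over its 17 libraries.

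**Figure D4:**
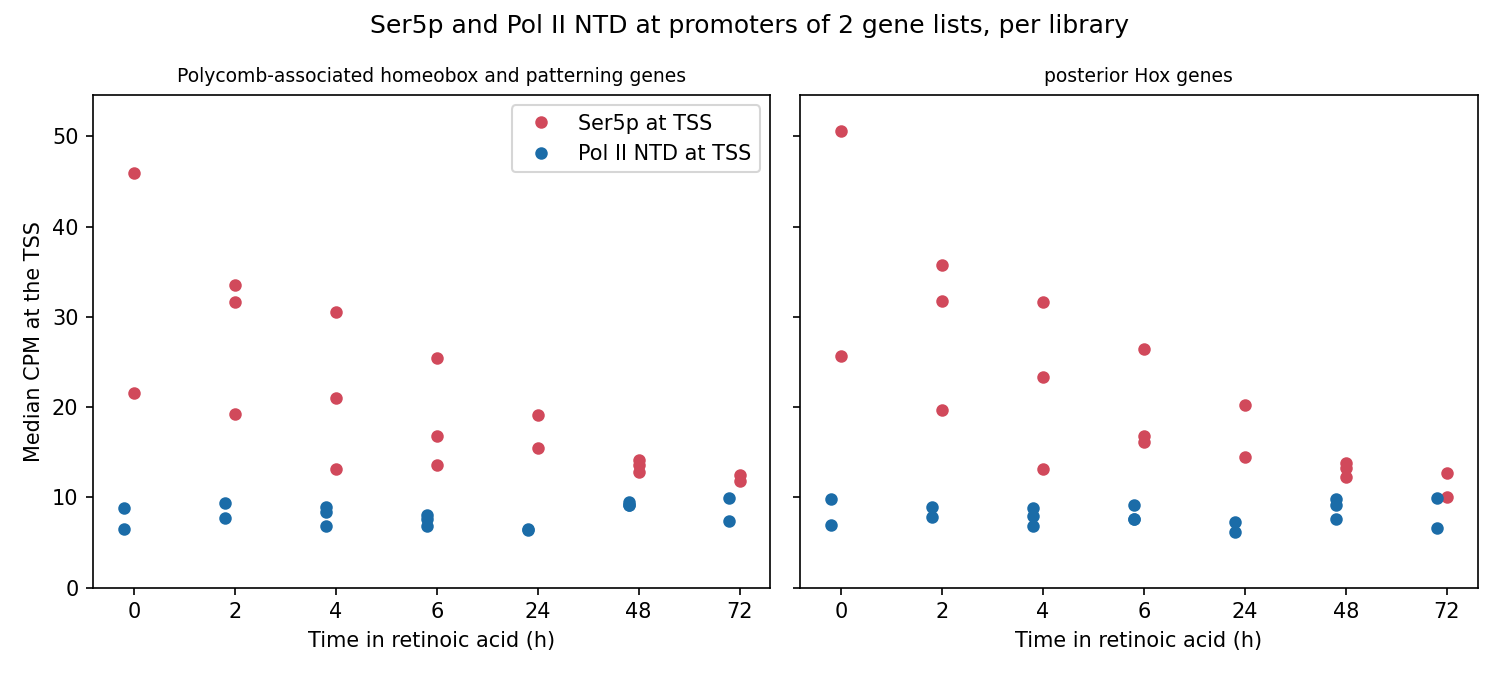
Median CPM at the TSS, per library, of the Polycomb-associated list and of the posterior Hox list, Ser5p in red and NTD in blue, against hours of RA drawn as evenly spaced categories. Ser5p over the Polycomb-associated list stood at 21.6 and 46.0 CPM at 0 h and at 12.5 and 11.8 CPM at 72 h, and NTD at 6.36 to 9.90 CPM throughout.

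Ser5p rose 10.4-fold at 72 h at Egr1 (3.38 ± 0.45, adjusted p = 4.57e-06), 5.64-fold at Fos (adjusted p = 8.03e-08) and 5.46-fold at Rarb (2.45 ± 0.33). It also rose at Cyr61 (2.73 ± 0.31), Fosb (2.57) and Jun (2.26). Of 16 immediate early genes 10 rose (11 adjusted over the list alone). The list median, 1.29, came with a camera adjusted p = 9.31e-14 (adjusted p = 0.0601 with an estimated correlation). Of 13 heat shock and p53 response genes 5 rose (9 adjusted over the list alone), with a camera adjusted p = 8.25e-06 and adjusted p = 0.346 with an estimated correlation. Mesoderm genes fell at 8 of 15 promoters, such as the primitive streak genes Eomes and Mixl1 (1 higher and 10 lower adjusted over the list alone). The list median, -1.10, came with a camera adjusted p = 1.91e-05 (adjusted p = 0.300 with an estimated correlation). Neural genes fell at 8 of 24 promoters, such as Neurog1 (1 higher and 11 lower adjusted over the list alone), with a camera adjusted p = 1.77e-04 and adjusted p = 0.347 with an estimated correlation. Formative genes fell at 7 of 14 while Sox4 rose (1 higher and 11 lower adjusted over the list alone), with a camera adjusted p = 1.77e-04 and adjusted p = 0.300 with an estimated correlation. General pluripotency genes fell at 5 of 10 (5 adjusted over the list alone), with a camera adjusted p = 7.99e-04 and adjusted p = 0.300 with an estimated correlation. These mesoderm, neural, formative and general pluripotency falls rest on 0 h libraries that differed in Ser5p over the Polycomb-associated list (46.0 and 21.6 CPM). The values of these lists without 0 h replicate 4 are not given here. In the RA list 5 rose and Aldh1a2 fell (5 and 1 adjusted over the list alone). The RA list had a median of -0.03, or 0.15 with the authors' scale factors, and camera pointed up (adjusted p = 0.193). Nanog had a Ser5p change of -0.02. Pou5f1 was not called without 0 h replicate 4 (-0.70) or 72 h replicate 1 (-0.60). Sox2 was not called without 0 h replicate 4 (-1.14, adjusted p = 0.0656), and Actb not without 72 h replicate 3 (0.94).

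In all, Ser5p was higher at 10, 4, 16, 1178, 2244 and 1672 transcripts at 2, 4, 6, 24, 48 and 72 h and lower at 0, 1, 2, 1028, 1760 and 1267. Over all times together 4753 were called. Beside the 0 lower calls of edgeR at 2 h, 2157 transcripts in either direction had an unadjusted p under 0.05, and DESeq2 called 33. At 2 h the calls numbered 0 without either 0 h library, and 3 without 2 h replicate 1 or 2 h replicate 3. At 4 h there were 24 higher and 344 lower without 0 h replicate 1, and 3 and 9 without 4 h replicate 1. The 4 h calls numbered 0 without 0 h replicate 4, 4 h replicate 3 or 4 h replicate 4. At 6 h there were 50 and 588 without 0 h replicate 1 and 53 and 139 without 6 h replicate 4. The 6 h calls numbered 9 and 0 without 6 h replicate 3, 3 and 0 without 0 h replicate 4, and 0 without 6 h replicate 1. At 24 h there were 361 and 956 without 0 h replicate 1, 47 and 8 without 0 h replicate 4, 1076 and 425 without 24 h replicate 2, and 23 and 2 without 24 h replicate 3. At 48 h there were 982 and 1382 without 0 h replicate 1 and 486 and 338 without 0 h replicate 4. The 48 h calls numbered 1159 and 1168 without 48 h replicate 2, and 1312 and 1039 without 48 h replicate 3. At 72 h there were 907 and 1251 without 0 h replicate 1, 524 and 237 without 0 h replicate 4, and 285 and 388 without 72 h replicate 3.

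The Ser5p splits also moved with the scaling, the tool and the model. With the authors' scale factors they were 14 higher and 5 lower at 6 h, 5960 and 324 at 24 h, 3307 and 854 at 48 h and 1691 and 735 at 72 h. With library totals they were 653 and 1368 at 24 h and 1404 and 1709 at 72 h. DESeq2 called 1730 higher and 10 lower at 24 h, 2098 and 1150 at 48 h, and 1411 and 847 at 72 h. Both 24 h libraries had higher enrichment indices (1.14 and 1.45) than those of 0 h (0.52 and 0.27). With the index as a covariate there were 36 higher and 55 lower at 24 h, 1353 and 1472 at 48 h, and 894 and 1162 at 72 h. With a replicate block there were 148 and 44 at 24 h. With the authors' factors the median log2 change of all transcripts stood at 0.19, 0.13, 0.21, 0.40, 0.23 and 0.17 at 2, 4, 6, 24, 48 and 72 h. With library totals it stood at -0.10 at 2 h, -0.11 at 6 h, -0.27 at 24 h and -0.17 at 48 and 72 h.

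Over gene bodies, NTD asked where polymerase entered transcription. At 6 h (n = 3) it rose at Stra8 (10.1 ± 0.274 to 40.1 ± 7.22 CPM, 3.95-fold, 1.98 ± 0.31, adjusted p = 0.0269) and Cyp26c1 (3.46-fold, 1.79 ± 0.20, adjusted p = 0.00482). It rose at Cd37 (1.50 ± 0.25), Camk2n1, an inhibitor of a calcium-dependent kinase (1.48 ± 0.21), Scube3, which encodes a secreted protein (1.30 ± 0.18), and Dock6, a guanine nucleotide exchange factor gene (1.21 ± 0.19). Cyp26a1 had a change of 2.82 ± 0.51 (adjusted p = 0.0735). None of these 6 calls was left without 0 h replicate 1 or without 0 h replicate 4, where Cyp26c1 stood at 1.84 (adjusted p = 0.149) and 1.75 (adjusted p = 0.181). Stra8 (1.94 and 2.12), Cd37 (1.53 and 1.45), Camk2n1 (1.48 and 1.33), Scube3 (1.29 and 1.24) and Dock6 (1.26 and 1.18) were not called without 6 h replicate 1 or 4. Stra8 (1.87), Cd37 (1.51) and Dock6 (1.20) were also not called without 6 h replicate 3. Of 21 RA genes Nrip1, Stra8 and Cyp26c1 rose (9 adjusted over the list alone), with a camera adjusted p = 4.03e-05 and adjusted p = 0.234 with an estimated correlation. Of 15 anterior Hox genes 0 passed at 6 h (7 higher adjusted over the list alone). The list median, 0.36, came with a camera adjusted p = 4.03e-05 (adjusted p = 0.685 with an estimated correlation). At 24 h (n = 2) 6 of 15 anterior Hox genes rose, such as Hoxa2 and Hoxb4 (9 adjusted over the list alone). The list median, 0.68, then came with a camera adjusted p = 1.57e-11 (adjusted p = 0.0738 with an estimated correlation). Of these genes 0 were called at 24 h without 0 h replicate 1 or 4 (medians 0.69 and 1.55), and 1 without 24 h replicate 3 (0.54).

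At 72 h (n = 2) NTD over gene bodies rose 7.34-fold at Fos (12.8 ± 0.465 to 94.2 ± 16.8 CPM, 2.88 ± 0.30, adjusted p = 1.54e-04) and 6.88-fold at Jun (2.78 ± 0.28). It also rose at Egr1 (3.66 ± 0.63), Cyr61 (3.16 ± 0.43), Fosb (2.99 ± 0.45) and Krt18 (2.72). It fell at Inhbb (-2.30 ± 0.21), Tdgf1 (-2.27 ± 0.45) and Nphs1 (42.9 ± 0.530 to 10.6 ± 1.15 CPM, -2.02 ± 0.13, adjusted p = 2.56e-06). Hsd17b14, a steroid dehydrogenase gene (-2.01), the noncoding RNA Platr10 (-1.99) and the stem cell chromatin factor gene Utf1 (-1.96) fell too. Esrrb, a nuclear receptor gene of naive pluripotency, fell (-1.08 ± 0.16, adjusted p = 0.00152), and Rarb had a change of 0.37 (adjusted p = 0.178). Without 0 h replicate 4, Egr1 (3.38, adjusted p = 0.0896), Fosb (2.79, adjusted p = 0.0510), Krt18 (2.67, adjusted p = 0.0529) and Tdgf1 (-1.98, adjusted p = 0.103) were not called. Pou5f1 was not called without 0 h replicate 4 (-0.57) or 72 h replicate 1 (-0.71). With only the libraries of 0 h and 72 h, Fos and Jun were called and Nphs1, Inhbb, Esrrb, Cyr61 and Utf1 were not.

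Of 18 primitive endoderm genes 13 rose at 72 h, such as the laminin genes Lama1 (1.57 ± 0.22, adjusted p = 0.00121) and Lamc1 and the transcription factor genes Gata4 and Gata6 (16 adjusted over the list alone). The list median, 0.76, came with a camera adjusted p = 2.11e-19 (adjusted p = 0.0255 with an estimated correlation). Gata6 (1.12 ± 0.22) was not called without 0 h replicate 1 (1.06, adjusted p = 0.109) or 0 h replicate 4 (1.20, adjusted p = 0.0896). Of 16 immediate early genes 12 rose (13 adjusted over the list alone). The list median, 1.52, came with a camera adjusted p = 3.49e-16 (adjusted p = 0.0255 with an estimated correlation). Of 9 Hox cofactors 3 rose, such as Meis1 and Meis2 (4 higher and 2 lower adjusted over the list alone), with a camera adjusted p = 1.42e-04 and adjusted p = 0.0396 with an estimated correlation. Of 15 anterior Hox genes 8 rose, such as Hoxa3 (2.62-fold, 1.39 ± 0.22, adjusted p = 0.00247) (10 adjusted over the list alone). The list median, 1.23, came with a camera adjusted p = 2.42e-11 (adjusted p = 0.0520 with an estimated correlation). Hoxa5 (1.82) was not called without 0 h replicate 1 (1.72, adjusted p = 0.0520) or 0 h replicate 4 (1.95, adjusted p = 0.0510). General pluripotency genes fell at 6 of 10 (6 adjusted over the list alone), with a camera adjusted p = 2.91e-07 and adjusted p = 0.104 with an estimated correlation. Naive pluripotency genes fell at 7 of 20 (7 adjusted over the list alone), with a camera adjusted p = 5.25e-06 and adjusted p = 0.226 with an estimated correlation.

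In all, NTD over gene bodies was higher at 0, 6, 22, 83, 549 and 915 transcripts at 2, 4, 6, 24, 48 and 72 h and lower at 0, 0, 0, 3, 644 and 523. Over all times together 2488 were called. Beside the counts of 0, edgeR had 498, 1245 and 2333 transcripts at an unadjusted p under 0.05 at 2, 4 and 6 h, and DESeq2 called 1, 96 and 161. At 4 h 0 were called without 0 h replicate 1, 0 h replicate 4, 4 h replicate 3 or 4 h replicate 4, and 12 without 4 h replicate 1. At 6 h 0 were called without either 0 h library, and 3, 5 and 6 without 6 h replicates 1, 3 and 4. At 24 h 0 were called without either 0 h library, and 11 without 24 h replicate 3. At 48 h there were 155 higher and 340 lower without 0 h replicate 1, and 103 and 76 without 0 h replicate 4. Without 48 h replicates 1, 2 and 3 there were 487 and 324, 377 and 986, and 406 and 291. With a replicate block there were 412 and 1278 at 48 h. At 72 h there were 188 and 178 without 0 h replicate 1 and 128 and 88 without 0 h replicate 4. DESeq2 called 405 and 30 at 24 h, and 1518 and 708 at 72 h. The 72 h calls numbered 243 and 656 without 72 h replicate 3, and 4053 and 1782 without 72 h replicate 1.

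Ser2p over gene bodies asked where elongating polymerase changed. At 24 h (n = 2) it rose 6.53-fold at Cyp26a1 (2.71 ± 0.40, adjusted p = 0.00504) and 4.70-fold at Hoxa2 (2.48 ± 0.228 to 11.6 ± 0.472 CPM, 2.23 ± 0.32, adjusted p = 0.00424). It rose at Jun (2.21 ± 0.32), Dusp6, an ERK phosphatase gene (1.46 ± 0.22), Dhrs3 (1.36 ± 0.24) and Nrip1 (51.7 ± 0.698 to 115 ± 3.07 CPM, 1.16 ± 0.14, adjusted p = 0.00297). Of 16 immediate early genes 12 rose (12 adjusted over the list alone). The list median, 1.45, came with a camera adjusted p = 2.65e-08 (adjusted p = 0.138 with an estimated correlation). Of 13 BMP and TGF-beta targets 7 rose (9 adjusted over the list alone), with a camera adjusted p = 4.85e-06 and adjusted p = 0.138 with an estimated correlation. Of 11 FGF-ERK feedback genes 5 rose (8 adjusted over the list alone), with a camera adjusted p = 1.08e-05 and adjusted p = 0.138 with an estimated correlation. Of 21 RA genes 7 rose (11 higher and 4 lower adjusted over the list alone), with a camera adjusted p = 0.00787 and adjusted p = 0.138 with an estimated correlation. Of 15 anterior Hox genes 7 rose (9 higher and 2 lower adjusted over the list alone), with a camera adjusted p = 0.00749 and adjusted p = 0.464 with an estimated correlation. Actb rose too (1.55 ± 0.32, adjusted p = 0.0190). At 24 h 2896 transcripts were higher and 1285 lower. This count was 973 and 306 without 0 h replicate 1, 2 and 0 without 0 h replicate 4, 756 and 50 without 24 h replicate 2, and 0 without 24 h replicate 3. The 2 libraries of 24 h had enrichment indices of -3.64 and -3.56, above those of 0 h (-4.11 and -4.45), and with the index as a covariate 86 transcripts were called. With the authors' scale factors the split was 3293 higher and 778 lower.

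At 72 h (n = 2) Ser2p rose 8.48-fold at Fos (4.31 ± 0.854 to 36.5 ± 0.813 CPM, 3.08 ± 0.40, adjusted p = 0.00117) and 7.54-fold at Jun (2.91 ± 0.31, adjusted p = 7.53e-04). It rose at Egr1 (3.65 ± 0.65), Fosb (3.13), Cyr61 (3.12) and the tropomyosin gene Tpm1 (2.40). Of 16 immediate early genes 10 rose (13 adjusted over the list alone). The list median, 1.60, came with a camera adjusted p = 2.28e-15 (adjusted p = 0.0444 with an estimated correlation). Of 18 primitive endoderm genes 6 rose (11 adjusted over the list alone), such as the laminin genes Lamb1 (2.23-fold, 1.16 ± 0.11, adjusted p = 2.25e-04) and Lama1 (1.25). The list median, 0.42, came with a camera adjusted p = 6.56e-10 (adjusted p = 0.111 with an estimated correlation). Of the Hox cofactors 3 rose, such as Meis2 (0.76 ± 0.09) and Meis1 (3 adjusted over the list alone), with a camera adjusted p = 0.00240 and adjusted p = 0.111 with an estimated correlation. Ser2p fell at Inhbb (-1.28 ± 0.20), Tet1, a methylcytosine dioxygenase gene (-1.16 ± 0.20), Tdh (-1.14 ± 0.14, adjusted p = 9.25e-04), Nphs1 (-1.01), Hsd17b14 (-0.91) and Zfp202 (-0.77). Without 0 h replicate 1 or 72 h replicate 3, Inhbb (-1.20 and -1.22), Tet1 (-0.94 and -1.28) and Nphs1 (-0.79 and -0.92) were not called. Cyr61 was not called without 0 h replicate 1 (3.13, adjusted p = 0.0646), nor Fosb without 0 h replicate 4 (2.87, adjusted p = 0.0671). Lama1 was not called without either (1.21 and 1.30, adjusted p = 0.0884 and 0.0600). Without 0 h replicate 1, 0 h replicate 4 or 72 h replicate 3, the calls of Egr1 (4.34, 3.17 and 2.82), Tpm1 (2.39, 2.40 and 1.30), Hsd17b14 (-0.80, -1.02 and -0.97) and Zfp202 (-0.64, -0.89 and -0.95) were lost. Zfp202 was also not called without 72 h replicate 1 (-0.61). With only the libraries of 0 h and 72 h, Fos and Jun were called, and Tdh, Lamb1 and Meis2 were not.

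Ser2p was called by edgeR at 0 transcripts at 2, 4 and 6 h, with 4365, 2976 and 4424 transcripts at an unadjusted p under 0.05 and 204, 78 and 172 calls by DESeq2. Without 2 h replicate 1 there were 315 higher and 10 lower at 2 h, and without 6 h replicate 4 there were 2 higher at 6 h. Ser2p was higher at 454 and lower at 111 transcripts at 48 h and 411 and 110 at 72 h, with 2418 called over all times together (1591 without 0 h replicate 4). DESeq2 called 827 and 163 at 48 h and 909 and 182 at 72 h. At 48 h there were 66 and 4 without 0 h replicate 1 and 71 and 16 without 0 h replicate 4. The 48 h calls numbered 748 and 186 without 48 h replicate 1, 150 and 19 without 48 h replicate 2, and 258 and 33 without 48 h replicate 3. At 72 h there were 36 and 2 without 0 h replicate 1 and 60 and 17 without 0 h replicate 4. The 72 h calls numbered 2117 and 710 without 72 h replicate 1, and 46 and 1 without 72 h replicate 3.

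**Figure D5:**
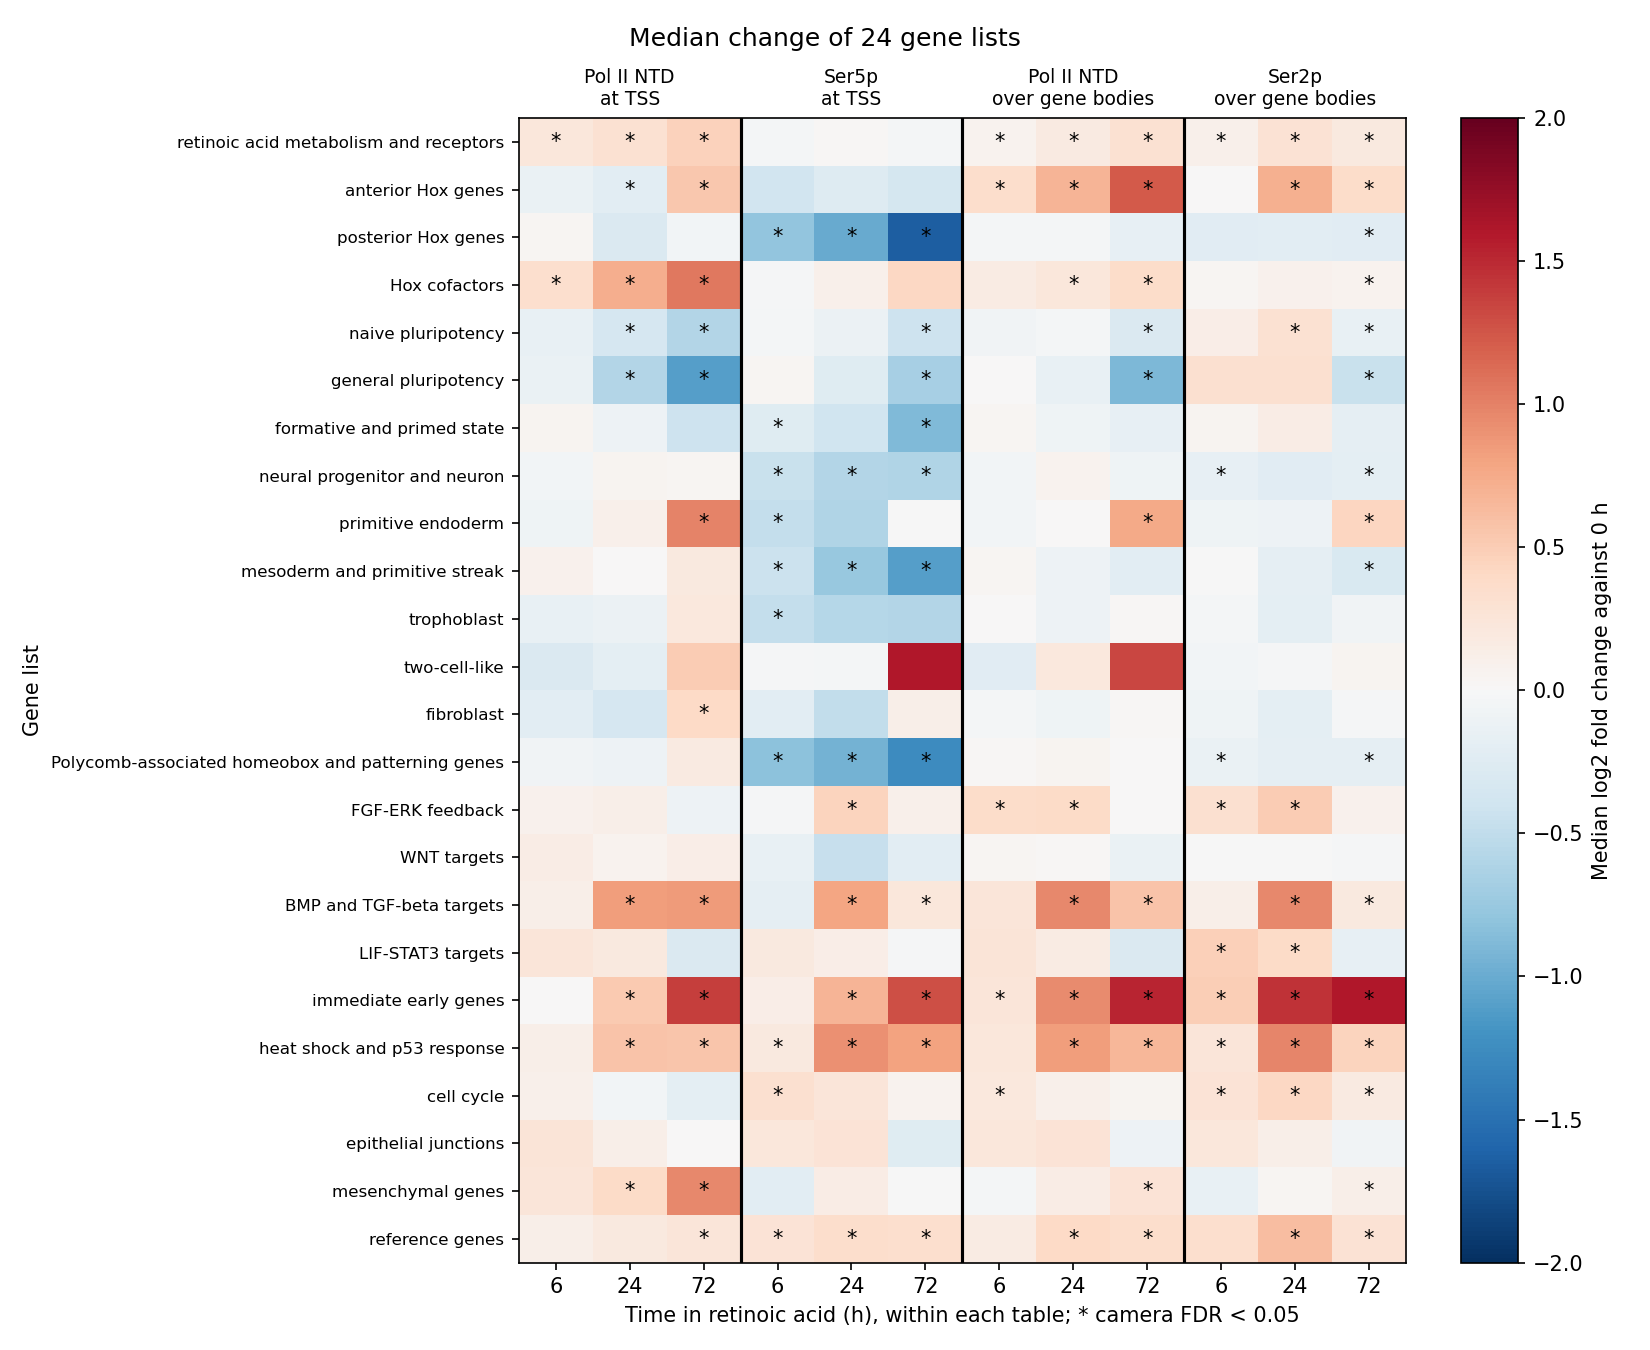
Heat map of the median log2 change of the 24 gene lists against 0 h at 6, 24 and 72 h in the 4 tables, on a colour scale from -2 to 2, with an asterisk where the camera test at the preset correlation passed. At 72 h the immediate early genes had medians of 1.38 (NTD at TSS), 1.29 (Ser5p), 1.52 (NTD over gene bodies) and 1.60 (Ser2p), and the Polycomb-associated list had -1.26 for Ser5p and 0.18 for NTD at the TSS.

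Whether Ser5p changed otherwise than total Pol II at the same promoters was tested as an interaction. At 72 h 23 transcripts of 14 genes had a lower change of Ser5p than of NTD. Among them were Fendrr (difference of log2 changes -3.06), Sox9, a transcription factor gene of several lineages (-2.93), Nr2f2, a nuclear receptor gene (-2.43), and Irx3 (-2.38). The eye patterning gene Vax2 with its antisense Vax2os (-2.62 and -2.72) and Meis1 (-1.56) were called too. At Meis1 NTD rose by 2.15 ± 0.26 while Ser5p had a change of 0.60 ± 0.23 (adjusted p = 0.0967). Beside the 23 calls, 0 went the other way, with 1900 transcripts at an unadjusted p under 0.05. There were 0 without Ser5p 0 h replicate 4, Ser5p 72 h replicate 1 or NTD 72 h replicate 3, and 0 with a replicate block. The median difference at the 23 transcripts was then -1.72, -2.40, -2.34 and -1.99, against -2.40 with all libraries (median SE 0.50, and 0.52, 0.56, 0.58 and 0.50 in those settings). Without Ser5p 0 h replicate 1 there were 1 higher and 362 lower. There were 3 lower without Ser5p 72 h replicate 3, 2 without NTD 0 h replicate 1 and 35 without NTD 72 h replicate 1. At 6 h edgeR called 0 (1087 at an unadjusted p under 0.05), 145 without NTD 0 h replicate 1 and 7 without Ser5p 0 h replicate 1. For Ser2p against NTD over gene bodies edgeR called 0 at 6 h and 0 at 72 h, with 440 and 895 at an unadjusted p under 0.05. It called 10 at 72 h without NTD 72 h replicate 1. DESeq2 was not run on these interactions.

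The ratio of NTD over the gene body to NTD at the TSS, tested with limma, rose at 62 and fell at 68 transcripts at 72 h (52 and 47 genes). It rose at Hoxa3 (1.87 ± 0.35, adjusted p = 0.0393), at Fos (0.77 ± 0.15, adjusted p = 0.0432), at the growth factor gene Bmp4 (1.63) and at Nelfa (1.40), which encodes a subunit of the negative elongation factor. There were 0 calls with a replicate block or without 0 h replicate 4, 2 higher and 2 lower without both 0 h replicate 4 and 72 h replicate 3, and 1 higher and 8 lower without 0 h replicate 1. The ratio calls numbered 30 and 13 without 72 h replicate 1, 10 and 5 without 72 h replicate 3, and 7 and 21 with library totals. At 6 h limma called 0, with 1612 transcripts at an unadjusted p under 0.05. Of the RA list 2 ratios rose and 1 fell adjusted over the list alone.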

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

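The tests that weigh explanations in this part, and the bounds they were judged by, were chosen only after the result was seen, while the interaction of antibody and time, the replicate block and leaving out each library were planned. That interaction was picked out because it differs between antibodies under the same contrast: at 72 h 23 transcripts, at Fendrr, Sox9, Nr2f2, Irx3, Vax2, Meis1 and other genes, had a lower change of Ser5p than of total Pol II, and none a higher one. With a replicate block 0 were called, and 0 without Ser5p 0 h replicate 4, Ser5p 72 h replicate 1 or NTD 72 h replicate 3, where the median difference at the 23 transcripts was -1.99, -1.72, -2.40 and -2.34 against -2.40 with all libraries.

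The pattern weighed is the lower Ser5p at Polycomb-associated promoters at 72 h, where all 30 genes lay below 0 with a median of -1.26 (quartiles -1.68 to -1.07, 24 called). High Ser5p in 0 h replicate 4 alone is argued against as the whole cause: without that library all 30 genes lay below 0 with a median of -0.80 (quartiles -1.05 to -0.52), though 5 were called, as the median SE went from 0.365 to 0.406 and the change shrank. A difference in enrichment between libraries is argued against in the same way, with a median of -0.97 (quartiles -1.25 to -0.74, median SE 0.367, 14 called) once the index was a covariate. A loss of Ser5p beyond that of total Pol II cannot be told apart from differences between libraries, because fewer than the 15 genes it needed were lower under 4 settings. NTD at the promoters of this list was low, with library medians of 6.36 to 9.90 CPM against a median of 15.3 CPM over transcripts. A fall of NTD could thus be missed. The difference from NTD had a median of -1.69 over 29 genes, 28 of them below 0 and 20 lower adjusted over the list alone. It was -1.05 (4 lower) without Ser5p 0 h replicate 4, -1.56 (9 lower of 30) without NTD 0 h replicate 4, -1.50 (13 lower of 30) without NTD 72 h replicate 1 and -1.76 (12 lower of 30) without both NTD libraries with extra promoter signal, and -2.11 (27 lower) without Ser5p 0 h replicate 1. Differences between Ser5p libraries that follow neither of these 2 settings stay open, since 0 h and 72 h have 2 libraries each and the set test reached adjusted p = 0.300 with an estimated correlation.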

How the results depend on the processing

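The authors' scale factors, the enrichment index, 1 transcript per gene and leaving out both NTD libraries with extra promoter signal were alternatives chosen only after the results were seen, and the others were planned. Of the counts of calls under all alternatives, 312 stayed within 1.5 times and 205 moved by more. For the named genes, 9375 values kept their side of the threshold, 569 lost it, 191 gained it and 12 changed sign after a call. For the lists, 667 values kept their side of the threshold, called or not, 178 lost a call, 16 gained one and 3 changed sign. With an estimated correlation 187 kept their side and 101 lost a call, and with fry 230 kept it, 55 lost a call and 3 gained one. Without 0 h replicate 1 or 4, the counts over all times were 4366 and 4651 for NTD at TSS, 4686 and 4060 for Ser5p and 1973 and 1897 for NTD over gene bodies, within 1.5 times, while Ser2p had 1937 and 1591 against 2418, the latter beyond 1.5 times. The planned stricter thresholds were not run. Except where a library left out or a smaller number of transcripts tested shows it, the cause was not tested. In the simulated TSS counts, with 200 transcripts changed, most 2-fold changes were missed, a share that need not hold where more transcripts change. Depth was not separated from the spread between libraries.

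A replicate block moved the counts of NTD at TSS to 282 at 24 h, of Ser5p to 54, 50, 161, 192 and 2532 at 2, 4, 6, 24 and 48 h and of NTD over gene bodies to 43, 98 and 35 at 4, 6 and 24 h. It moved those of Ser2p to 30, 11, 29, 258 and 314 at 2, 6, 24, 48 and 72 h, of the interaction of Ser5p and NTD to 16 at 6 h and 0 at 72 h, and of the ratio at 72 h to 0. In the set test with the block, cell cycle genes at 24 h in NTD at TSS (adjusted p = 0.0398) and over gene bodies (0.00681) and primitive endoderm genes in Ser2p at 24 h (0.0180) changed direction. Libraries of the same number share only a number: their deviations correlated above 0.1 in 18 of 32 pairs for NTD at TSS (-0.19 to 0.35), 26 of 32 for NTD over gene bodies (-0.44 to 0.62), 17 of 37 for Ser2p (-0.47 to 0.61) and 18 of 37 for Ser5p (-0.23 to 0.43), and 24 h has no number in common with 0 h. The block also moved the split of NTD over gene bodies at 48 h to 412 higher and 1278 lower.

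The authors' scale factors gave 136, 1567, 1214 and 2873 calls for NTD at TSS at 4, 48 and 72 h and over all times, 2, 0 and 6284 for Ser5p at 2, 4 and 24 h, and 0 for NTD over gene bodies at 4 h. Library totals gave 8 for Ser5p at 4 h, 3 for Ser2p at 6 h, 15 for the interaction of Ser5p and NTD at 72 h and 28 for the ratio at 72 h. DESeq2 size factors in edgeR gave 11 for NTD over gene bodies at 4 h, and no filter gave 11 there and 11 for the interaction of Ser5p and NTD at 72 h. A pseudocount of 2 CPM gave 207 for the ratio at 72 h.

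With the enrichment index as a covariate there were 49 calls for NTD at TSS at 2 h, 20, 28 and 91 for Ser5p at 2, 4 and 24 h, 138, 385, 459, 1049, 6332 and 6732 for NTD over gene bodies at the 6 times and 9207 over all, and 42, 34, 39, 86, 3392 and 2931 for Ser2p at the 6 times and 7729 over all. With 1 transcript per gene, where fewer transcripts are tested, there were 304, 1996, 1842 and 3009 for NTD at TSS at 24, 48 and 72 h and over all, 1434 and 2639 for Ser5p at 24 and 48 h, 718, 899 and 1533 for NTD over gene bodies at 48 and 72 h and over all, and 10, 3, 2563 and 1573 for Ser2p at 2, 6 and 24 h and over all.

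With only the libraries of the 2 times there were 3 and 1779 for NTD at TSS at 2 and 72 h, 2, 9, 154 and 3515 for Ser5p at 2, 4, 6 and 24 h, 78, 59, 933, 2452, 565 and 4 for NTD over gene bodies at the 6 times, and 62, 586, 9056, 196 and 2 for Ser2p from 4 h on. Without both NTD libraries with extra promoter signal there were 9, 34, 36, 199, 1607 and 801 for NTD at TSS and 0, 0, 18, 456 and 189 for its gene bodies from 4 h on. That setting gave 0 for the interaction of Ser5p and NTD at 72 h, and 2 and 4 for the ratio at 6 and 72 h, and Hoxb3 at 6 h (0.18) and Tbx6 at 72 h (-0.0763) then changed sign at the TSS.

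DESeq2 gave 3, 68, 71 and 179 for NTD at TSS at 2, 4, 6 and 24 h, 33, 33 and 73 for Ser5p at 2, 4 and 6 h, 1, 96, 161, 435 and 2226 for NTD over gene bodies at 2, 4, 6, 24 and 72 h, and 204, 78, 172, 990 and 1091 for Ser2p at 2, 4, 6, 48 and 72 h. Its likelihood ratio test over all times gave 4294 for NTD over gene bodies and 4255 for Ser2p.

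Leaving out 1 library gave, from 2 h to 72 h, 2 to 182, 18 to 231, 22 to 222, 21 to 394, 1237 to 2492 and 1566 to 3047 calls for NTD at TSS, and 0 to 7, 0 to 368, 0 to 638, 25 to 1501, 824 to 4860 and 673 to 3620 for Ser5p. For NTD over gene bodies it gave 0 to 12, 0 to 6, 0 to 62, 179 to 1363 and 216 to 5835 from 4 h on and 1765 to 5125 over all times. For Ser2p it gave 0 to 325 at 2 h, 0 to 2 at 6 h, 0 to 1279 at 24 h, 70 to 934 at 48 h, 38 to 2827 at 72 h and 1429 to 3438 over all times. It gave 0 to 145 and 0 to 363 for the interaction of Ser5p and NTD at 6 and 72 h, 0 to 10 for that of Ser2p and NTD at 72 h, and 0 to 43 for the ratio at 72 h. A library alone at its time is assumed to vary like the others. Named genes that changed sign at the TSS at 72 h ranged from a value without 72 h replicate 3 to one without 0 h replicate 4: Cdh11 from -1.74 to 2.65, Hoxb3 from -0.995 to 2.35, Hoxb5 from -2.16 to 1.67, Ntsr1 from -3.25 to 2.36, Pak3 from -2.11 to 2.46, Prlr from -3.14 to 2.11, Scnn1g from -2.86 to 2.93 and Sorcs3 from -2.27 to 1.84. At 6 h Hoxb3 ranged from -3.03 without 0 h replicate 1 to 0.18 without 0 h replicate 4. Fn1 over the gene body at 72 h stood at -0.43 without 72 h replicate 3.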

Other observations

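The tests of gene families and those that weigh explanations in this part were chosen only after the results were seen, while comparing each time with 0 h and leaving out each library were planned. The 5 gene families were picked after looking at the calls. Replication-dependent histone genes, whose proteins package new DNA, rose in NTD at the TSS at 4 of 61 promoters at 6 h (median 0.50, camera adjusted p = 1.24e-26, adjusted p = 0.304 with an estimated correlation). At 6 h 0 were called without 0 h replicate 4 (0.35). At 72 h 42 were higher (median 0.82, adjusted p = 0.244 with an estimated correlation), and 6 without 0 h replicate 4 (0.67) or 72 h replicate 3 (0.36). Ser5p was higher at 40 at 72 h (1.02, adjusted p = 0.209 with an estimated correlation), at 3 without 0 h replicate 4 (0.74), at 1 without 72 h replicate 3 (0.48) and at 24 with the enrichment index as a covariate (0.53). Similar copies and overlapping windows can share reads, so the 61 promoters may not all be independent. Genes of the amino acid response, which supply amino acids and charge transfer RNAs, fell at 11 of 15 promoters in NTD at 48 h (median -1.27, camera adjusted p = 2.67e-12, adjusted p = 0.0722 with an estimated correlation) and at 7 in Ser5p (adjusted p = 0.200 with an estimated correlation). In NTD 8 to 12 were lower with any 1 library of 0 h or 48 h left out, and in Ser5p 4 (without 48 h replicate 2) to 8. Ribosomal protein genes fell at 28 of 79 promoters in NTD at 48 h (median -0.51, adjusted p = 0.247 with an estimated correlation), and at 15, 6, 13 and 18 without 0 h replicate 1, 0 h replicate 4, 48 h replicate 1 and 48 h replicate 3.

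Targets of SRF and YAP, the transcription regulators of cytoskeletal tension, were higher at 72 h at 15 of 20 promoters in NTD (median 1.13, adjusted p = 0.0792 with an estimated correlation), 15 in Ser5p (1.27, adjusted p = 0.0547 with an estimated correlation), 12 over gene bodies in NTD and 10 in Ser2p (1.06). Without 72 h replicate 3 these were 6, 7, 4 and 1, and without 0 h replicate 1 9, 12, 3 and 0. They were 16, 11, 5 and 3 without 0 h replicate 4. This list was made after Cyr61, Tpm1 and Actb had been seen to rise, so its count is not independent of those genes. Olfactory receptor genes, which stem cells do not use, were lower at 52 of 987 promoters in Ser5p at 24 h (median -0.75). With the enrichment index as a covariate they were lower at 0 (-0.10). As the index is made from the same counts and was higher in both 24 h libraries, they cannot separate enrichment from a response. They were lower at 1 without 0 h replicate 4 (-0.72), 20 without 0 h replicate 1, 31 without 24 h replicate 2 and 0 without 24 h replicate 3 (-0.62).

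The lower NTD calls at promoters at 6 h (118 transcripts) were weighed first. A loss of Pol II after RA is argued against, since the median log2 of 0 h replicate 1 over the 6 h libraries was 0.0445 (quartiles -0.21 to 0.34) where the loss would need both 0 h libraries to stand above. Signal present in 0 h replicate 4 and not in 0 h replicate 1 accounts for the values: that library stood 6.41-fold above replicate 1 (median log2 2.68), and with 0 h replicate 4 left out 2 lower calls were made against 179 with 0 h replicate 1 left out. The signal came back in 72 h replicate 3 (2.48 over replicate 1), where 97 transcripts lay 4-fold above the other library against 126 in 0 h replicate 4, with 80 in both and 0.384 for independent lists. In 72 h replicate 1 202 and in 2 h replicate 1 51 transcripts lay 4-fold above, 0 of them among the 126. Over gene bodies 0 h replicate 4 lay 0.45 above replicate 1. A difference of the 0 h replicate 4 culture cannot be told apart from a difference of that precipitation, because Ser5p there differed by a median of 0.17 (quartiles -0.26 to 0.50) and the labels do not say whether both antibodies saw the same chromatin.

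The 4181 Ser2p calls at 24 h were weighed next. A difference in enrichment could account for a part of the values. Both 24 h libraries had indices above those of 0 h (lowest -3.64 at 24 h, highest -4.11 at 0 h). With the index as a covariate 86 calls were made. The index comes from the same counts and sets 24 h apart from 0 h. The covariate could therefore take up a response too. The median size of the change at the called transcripts went from 0.53 (SE 0.14) to 0.18 (SE 0.11) in the called direction, and what is left was not explained. A response to RA cannot be told apart from a difference in enrichment, because both libraries of 24 h share the high index. Within other times the library with the higher index also stood higher at the transcripts called higher at 24 h. The difference was 0.37 in 2 h replicate 3 over replicate 1, 0.33 in 72 h replicate 3 over replicate 1 and 0.37 in 48 h replicate 2 over replicate 1. The median change of those transcripts at 24 h was 0.65, larger than these differences.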
